A study of Mus musculus with 24 samples.

How the data were processed

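Gene expression was measured by RNA-seq in the prefrontal cortex of adult male wild-type mice. The 24 libraries fell into 4 groups of 6, named here by rearing and supplement: Control, MS (maternal separation, an early-life stress in which pups are kept apart from the dam), Control_EC12 and MS_EC12. EC12 stands for the EC-12 preparation of killed Enterococcus faecalis, a gut bacterium, which was given for 5 weeks per the labels. Groups and replicate numbers were taken from the labels. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, part of which may be technical.

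Per the labels' protocols, RNA was extracted with ISOGEN II and libraries were made with a stranded mRNA kit. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b, DESeq2 and the genome build mm10. Their roles and parameters, the counting rule and its strand setting are not given in the sources used here. The deposited table holds whole-number read counts per gene, which the authors left unnormalized, for 45777 genes with NCBI Gene identifiers. It also holds TPM values that the authors made from their own gene models per the file headers. The counts were used for every main result and the deposited TPM values for an alternative. A second deposited sheet pairs column names with groups and holds no measurement. No column was left without a sample and no row lacked a gene.

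Total counts ran from 26250197 to 39252382 per library. Depth of this order leaves genes with counts in single digits imprecise, so they were removed with filterByExpr in edgeR (minimum count 10, minimum total 15), which left 18380 genes. No libraries were duplicates: the smallest chi-square per gene between any pair was 5.13. Identifiers of 99.77% of the genes matched the RefSeq gene table of GRCm38.p6, the assembly behind mm10, from which coordinates were taken. Of the genes named below, those whose span overlaps another protein-coding gene were 4930445K14Rik with Pcif1, Plin4 with Hdgfl2, Hspa5 with Rabepk, Slc5a3 with Mrps6, and Pclaf with Trip4. Reads of such pairs, of gene copies that are nearly identical (haemoglobin, class I histocompatibility and histone genes) and of ribosomal protein genes with processed pseudogenes could have been split between copies, so their values are less certain.

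Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, 1 coefficient per group and all 24 libraries in the same fit. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 counted as a change. Log2 fold changes are given with their standard errors (SE) and n = 6 libraries per group, and CPM values (counts scaled to library size) with the SD. Log2 CPM values used a prior count of 2. The comparisons were MS with Control, Control_EC12 with Control, MS_EC12 with MS, with Control and with Control_EC12, and the interaction of rearing and supplement. On simulated counts with 200 of 18380 genes changed, the fit recovered 56% of changes of 1.5-fold and 91% of 2-fold changes for MS against Control, with 6 false calls. The shares were 70% and 89% with 6 false calls for MS_EC12 against MS, 56% and 94% with 5 for Control_EC12 against Control, 59% and 91% with 2 for MS_EC12 against Control, and 64% and 92% with 10 for MS_EC12 against Control_EC12. The simulated genes were drawn independently of one another. They lacked the dependence of libraries on GC content described below, so these shares and false calls do not cover its effect.

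Lists of marker and pathway genes, 39 in all, covered pathways, cell classes of the cortex, tissues that a dissection could carry in, and RNA or animal state. The sex-linked list was not tested. The others were tested with camera in limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists, with at least 5 measured members. Where a list is described, the count of members passing is also given adjusted over the list alone, and the adjusted p of camera with an estimated correlation stands beside it. No list call in any of the 6 comparisons held with an estimated correlation. The mean log2 CPM of each list per library was compared between groups with exact 2-sided permutation tests, whose smallest p for 6 against 6 libraries is 0.00216.

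The groups, comparisons, tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule named, per comparison, the 10 genes of smallest p among those that rose and among those that fell. Where fewer than 5 passed in a direction, the 5 of smallest p were eligible and are said not to pass. It further allowed up to 4 members of a list, passing ones first, then by smallest p, and 12 candidate genes: Oxtr, Avpr1a, Adrb3, Bdnf, Fos, Arc, Egr2, Nr3c1, Crhr1, Fkbp5, Mbp and Il1b. Predicted gene models were named only among the 3 smallest p. Genes named outside the rule are said to have been chosen after their values were seen. The gene counts include 1 gene that is not reported here.

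Libraries differed in how expression depended on the GC content of transcripts. For each library, the deviation of log2 CPM from the mean of all libraries was regressed on GC content (per 10 percentage points) and log2 length, over 12215 genes with a mean log2 CPM above 2. GC content came from GENCODE transcripts and was known for 91.9% of the genes tested. The slope on GC content was above 0 in 7 libraries and below 0 in 17. Each count and list was therefore computed again on the 17 libraries of slope below 0, of which 6 were Control, 5 MS, 4 Control_EC12 and 2 MS_EC12, with 19098 genes tested. This alternative, a model term for the sign of the slope, GC and length slopes or spline offsets (5 degrees of freedom) in the fit, the means of 2 lists (immediate early and glucocorticoid-induced genes) with such a spline trend subtracted from each library, limma-trend on log2(TPM + 1), the 7 libraries alone, and removal of ribosomal RNA and mitochondrial genes were chosen after the data were seen.

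Alternatives planned in advance were RLE size factors, no filter on low counts, DESeq2 1.42.0, voom with sample quality weights, fits of only the groups compared, the replicate number as a block, 3 surrogate variables from sva 3.50.0, an adjusted p under 0.1, and the removal of each library in turn. For lists they were an estimated correlation, the fry test, RLE size factors and the block.

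To ask whether the supplement moved genes opposite to maternal separation, log2 fold changes of MS against Control and of MS_EC12 against MS were correlated across genes. The MS libraries enter both with opposite sign, so chance values were simulated by regrouping libraries with the group effects removed. The responses to the supplement in Control-reared and MS-reared mice share no library, and their correlation was tested by permuting labels within each rearing. Genes are not independent replicates, and both tests therefore permute libraries. Library measures, GC content and plots were made with python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.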

Results

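The series measured gene expression in the prefrontal cortex of male mice reared normally or with maternal separation, with or without the EC-12 supplement, in 6 libraries per group. Total counts per library ran from 27229269 to 36336886 in Control, from 27772142 to 33710435 in MS, from 26250197 to 33899807 in Control_EC12 and from 29804781 to 39252382 in MS_EC12. Libraries correlated with one another at 0.917 to 0.9957 across genes in log2 CPM. The first principal component held 33.3% of the variance and the second 8.5%. Transcripts of the mitochondrial protein genes made up 6.91 ± 0.547%, 6.68 ± 0.374%, 7.61 ± 1.51% and 7.54 ± 0.686% of counts in the same order of groups (SD, n = 6).

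The slope of expression on GC content set some libraries apart from the rest. It was above 0 in 0 Control, 1 MS, 2 Control_EC12 and 4 MS_EC12 libraries. The group means were −0.114 ± 0.0294, −0.107 ± 0.192, −0.00606 ± 0.243 and 0.228 ± 0.341 log2 units per 10 percentage points of GC (SD, n = 6). Exact permutation of the slope of MS_EC12 against that of MS gave p = 0.0584, against Control p = 0.0606 and against Control_EC12 p = 0.206, and none of the 5 comparisons passed after adjustment (adjusted p from 0.152 to 1). Because 4 of the 7 libraries above 0 were MS_EC12, each comparison was also made in the 17 libraries of slope below 0. Among those 17 the slope still parted some groups. It was lower in every MS library (−0.219 to −0.156) and in both MS_EC12 libraries (−0.182 and −0.17) than in every Control library (−0.148 to −0.0761), and lower in both MS_EC12 libraries than in every Control_EC12 library (−0.16 to −0.0893). Exact permutation gave p = 0.00433 for MS against Control, 0.0714 for MS_EC12 against Control and 0.133 for MS_EC12 against Control_EC12.

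**Figure D1:**
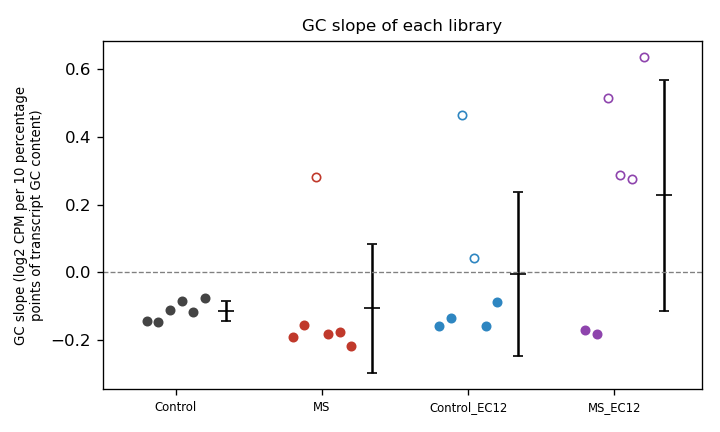
Slope of log2 expression on transcript GC content (log2 units per 10 percentage points) for each of the 24 libraries by group, with open markers for the 7 libraries of slope above 0 and the bar at the right of each group giving the mean ± SD of 6 libraries. Control libraries lie near −0.114, while 4 of the 6 MS_EC12 libraries lie above 0.

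The first comparison addressed the effect of maternal separation on mice without the supplement. Bhlhe40, a helix-loop-helix repressor of the circadian clock that is also induced by neuronal activity, fell in MS from 138 ± 10.9 to 81.9 ± 7.78 CPM (SD, n = 6), a log2 fold change of −0.76 ± 0.108 (SE; adjusted p = 0.0043). Foxo6, a forkhead transcription factor of the brain, fell by 0.75 on the log2 scale (adjusted p = 0.0251), and Banp, a nuclear protein that binds CpG-containing promoter motifs, fell from 27.7 ± 2.16 to 19.4 ± 2.22 CPM (log2 fold change −0.52 ± 0.0905, adjusted p = 0.0251). Pdgfb, which encodes a subunit of platelet-derived growth factor, changed by −0.58 ± 0.108 (adjusted p = 0.0471). The gene model 4930445K14Rik rose by 0.77 ± 0.113 (adjusted p = 0.0043) and Lrch4, a leucine-rich repeat protein, by 2.14 ± 0.376 from a low level of 1.07 ± 0.402 CPM (adjusted p = 0.0251). Each change was in the same direction in 6 of 6 MS libraries, except Lrch4, which was higher in 5 of 6.

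These 6 genes were all that passed in MS against Control, 2 higher and 4 lower, with 662 genes at an unadjusted p under 0.05. Bhlhe40 lies on chromosome 6 from 108660629 to 108666925 (Gene ID 20893, GRCm38), Banp on chromosome 8 from 121947972 to 122029260 (Gene ID 53325), Foxo6 on chromosome 4 from 120267078 to 120287261 (Gene ID 329934), and Pdgfb on chromosome 15 from 79995865 to 80024614 (Gene ID 18591). The next genes by p did not pass: Nat8f3 (log2 fold change 0.53), Creb5 (0.79) and Rasgef1b (0.45) at an adjusted p of 0.0969, and Klf10 (−0.59) at 0.0844. Of the candidate genes none passed. Their log2 fold changes were −0.69 for Egr2 (adjusted p = 0.688), −0.46 for Fos (adjusted p = 0.796) and −0.49 for Arc, −0.52 for Il1b, −0.17 for Crhr1, −0.11 for Nr3c1, −0.08 for Oxtr, the oxytocin receptor, −0.04 for Avpr1a, 0.03 for Bdnf and 0.33 for Adrb3 (adjusted p = 1 for each of these).

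Activity-induced immediate early genes were lower in MS as a list, with a median log2 fold change of −0.302 over 35 members, of which 6 were positive (camera adjusted p = 2.3e-18; adjusted p = 0.0605 with an estimated correlation). No member passed over all genes, and 13 passed with a lower level when adjusted over the list alone. Nr4a3 stood at −0.66 ± 0.139 (adjusted p = 0.0969), Egr4 at −0.65 and Egr1 at −0.46. Circadian clock genes were also lower, with a median of −0.14 over 18 members, 1 of which fell over all genes (Bhlhe40) and 4 when adjusted over the list alone (camera adjusted p = 2.94e-08; adjusted p = 0.0605 with an estimated correlation). Per1 stood at −0.55 ± 0.112 (adjusted p = 0.0944) and Nr1d1, a repressor in the second loop of the clock, at −0.47 ± 0.101 (adjusted p = 0.0973), while Per2 stood at −0.40 (adjusted p = 0.909).

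Further shifts in MS concerned other tissues and RNA state. Meningeal and perivascular fibroblast genes had a median of −0.188 over 23 members (adjusted p = 2.28e-06; 0 passed, 1 lower over the list alone; adjusted p = 0.51 with an estimated correlation) and endothelial genes −0.165 over 20 (adjusted p = 0.0115; 0 passed; adjusted p = 0.793 with an estimated correlation). Nuclear genes of the respiratory chain had a median of 0.076 over 74 members and ribosomal protein genes 0.0955 over 77, with 0 members passing in either (adjusted p = 3.25e-08 and 1.41e-10; adjusted p = 0.793 with an estimated correlation for both). Striatal genes had a median of 0.116 over 25 members (adjusted p = 0.00526; adjusted p = 0.952 with an estimated correlation) and hypothalamic and septal genes 0.344 over 17 (adjusted p = 0.0078; adjusted p = 0.793 with an estimated correlation), where Oxt, the gene of oxytocin, stood at 2.44 ± 1.24 without passing. No member of these 2 lists passed. The mean log2 CPM of hypothalamic and septal genes was high in MS replicate 1 (3.23) and MS replicate 4 (2.719). The other MS libraries lay within the Control range (1.57 to 2.272).

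In the 17 libraries of GC slope below 0, 83 genes differed between MS and Control, 16 higher and 67 lower, including all 6 above, with 2052 genes at an unadjusted p under 0.05. There Per1 was called at −0.57 (adjusted p = 0.000557), Nr1d1 at −0.52 (adjusted p = 0.000484), Egr4 at −0.70 (adjusted p = 0.0112), Egr1 at −0.52 (adjusted p = 0.0163) and Nr4a3 at −0.64 (adjusted p = 0.0161). The immediate early list had a median of −0.351 with 5 members called lower, and the clock list −0.157 with 4. By the preset-correlation test the striatal list lost its call there (median 0.0563, adjusted p = 0.0973). The other 5 lists passed, with medians of −0.147 for meningeal fibroblasts, −0.176 for endothelium, 0.0534 for the respiratory chain, 0.0743 for ribosomal proteins and 0.336 for hypothalamic and septal genes. The number of genes changed, MS vs Control, was 2 in place of 6 without Control replicate 3, 5 or 6, and 2 without MS replicate 4 or 5.

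The supplement alone was compared in normally reared mice, Control_EC12 against Control. Per2, a core repressor of the circadian clock, fell from 61.9 ± 7.88 to 29.4 ± 6.76 CPM (log2 fold change −1.08 ± 0.141, adjusted p = 0.00106). The ubiquitin-specific peptidase Usp43 rose from 2.72 ± 0.291 to 4.61 ± 0.801 CPM (0.76 ± 0.119, adjusted p = 0.00571). Banp fell from 27.7 ± 2.16 to 17.8 ± 1.4 CPM (−0.64 ± 0.0908, adjusted p = 0.0021). Each of these 3 genes moved in the same direction in 6 of 6 libraries (SD, n = 6).

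Per2 lies on chromosome 1 from 91415977 to 91459351 (Gene ID 18627) and Usp43 on chromosome 11 from 67854523 to 67922153 (Gene ID 216835). In all, 4 genes passed, 2 higher and 2 lower, with 1642 genes at an unadjusted p under 0.05. Genes next in order did not pass: Prkab1 stood at 0.50 (adjusted p = 0.0542), Magef1 at 0.42, Aldh3b1 at 0.43, Map3k13 at −0.47, and the endoplasmic reticulum chaperones Pdia4 and Hspa5 at −0.48 and −0.64 (adjusted p = 0.0669 for both). Of the candidates none passed, with Fkbp5 at −0.21 (adjusted p = 0.33), Fos at 0.41 (adjusted p = 0.411), Adrb3 at 0.53 (adjusted p = 0.397) and Oxtr at −0.23 (adjusted p = 0.56).

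Genes of antigen presentation and complement were higher with the supplement in normally reared mice, with a median of 0.339 over 21 members, 18 of them positive (camera adjusted p = 8.99e-10; adjusted p = 0.162 with an estimated correlation). None passed over all genes and 11 passed with a higher level when adjusted over the list alone. Cd74, the invariant chain of class II molecules, stood at 0.69 (adjusted p = 0.164), H2-Ab1 at 0.66, H2-Q4 at 0.57 and the peptide transporter Tap1 at 0.53. Interferon-stimulated genes had a median of 0.227 over 31 members, with 29 positive, 0 passing and 5 higher over the list alone (adjusted p = 0.000183; adjusted p = 0.353 with an estimated correlation); Oasl2 stood at 0.69 and Irf7 at 0.67. Microglial genes had a median of 0.139 over 21 members, with 0 passing (adjusted p = 0.00215; adjusted p = 0.353 with an estimated correlation).

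Clock genes were lower, with a median of −0.191 over 18 members. Per2 passed over all genes, and 6 lower and 1 higher passed over the list alone (camera adjusted p = 3.7e-06; adjusted p = 0.162 with an estimated correlation). Cry1 stood at −0.42 (adjusted p = 0.0669), Bhlhe40 at −0.50 ± 0.107 (adjusted p = 0.074) and Nfil3, which is expressed out of phase with the Per genes, at 0.47 (adjusted p = 0.174). Heat shock and chaperone genes had a median of −0.158 over 20 members (0 passed, 1 lower over the list alone, adjusted p = 4.79e-05; adjusted p = 0.193 with an estimated correlation).

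Synaptic lists shifted down with 0 members passing over all genes. The medians were −0.091 for 31 postsynaptic genes (adjusted p = 0.00104), among which Homer1 stood at −0.60 ± 0.124, −0.0487 for 30 genes of synaptic vesicles (adjusted p = 0.0344), −0.17 for 16 GABA receptor genes (adjusted p = 0.0308) and −0.103 for 24 glutamate receptor genes (adjusted p = 0.0328). Neurotrophin signalling had −0.127 over 20 (adjusted p = 0.00908) and neuropeptides of social behaviour −0.128 over 30 (adjusted p = 0.0116). With an estimated correlation their adjusted p ran from 0.353 to 0.47. Over the list alone, 1 postsynaptic gene was higher and 1 lower and none passed in the other 5 lists.

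RNA state and neighbouring tissues moved too. Ribosomal protein genes had a median of 0.217 with 77 of 77 positive (adjusted p = 1.54e-19) and nuclear respiratory chain genes 0.145 over 74 (adjusted p = 4.69e-09), with 0 passing in either. Olfactory bulb genes had a median of 0.805 with 15 of 15 positive (adjusted p = 9.19e-06), among them Th at 0.86, Nmb at 0.94 and Tbx21 at 1.16, none of which passed. Meningeal fibroblast genes stood at 0.244 over 23 (adjusted p = 1.16e-05, 3 higher over the list alone, with Slc6a13 at 0.51), ependymal genes at 0.28 over 16 (adjusted p = 0.028) and mural genes at 0.146 over 15 (adjusted p = 0.028, 1 higher over the list alone). Striatal genes stood at −0.107 over 25 (adjusted p = 0.00296) and junction genes of the blood-brain barrier at −0.108 over 16 (adjusted p = 0.0344). None of these lists held with an estimated correlation, where their adjusted p ran from 0.353 to 0.56.

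Among the 17 libraries, 87 genes differed between Control_EC12 and Control, 23 higher and 64 lower, including the 4 of all libraries, with Per2 at −0.95 (adjusted p = 0.00108), Banp at −0.69 and Hspa5 now called at −0.57 (adjusted p = 0.0061). The antigen list had a median of 0.235 there, the interferon list 0.303, the clock list −0.176 with 4 members called lower, the olfactory bulb list 0.985, and the ribosomal list 0.0474 in place of 0.217. The respiratory chain list changed sign, to −0.014 (adjusted p = 0.203). Other lists lost their call: microglia (median 0.067, adjusted p = 0.0711), GABA receptors (−0.0245, adjusted p = 0.404) and glutamate receptors (−0.0158, adjusted p = 0.651). So did neurotrophin signalling (−0.0233, adjusted p = 0.198), barrier junctions (−0.0517, adjusted p = 0.255), mural cells (0.144, adjusted p = 0.148) and ependyma (0.179, adjusted p = 0.226). The postsynaptic (−0.0491), synaptic vesicle (−0.0479), neuropeptide (−0.198), heat shock (−0.122), meningeal fibroblast (0.23) and striatal (−0.337) lists passed. The number of genes changed, Control_EC12 vs Control, was 24 in place of 4 without Control replicate 1 and 7 without Control_EC12 replicate 3.

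**Figure D2:**
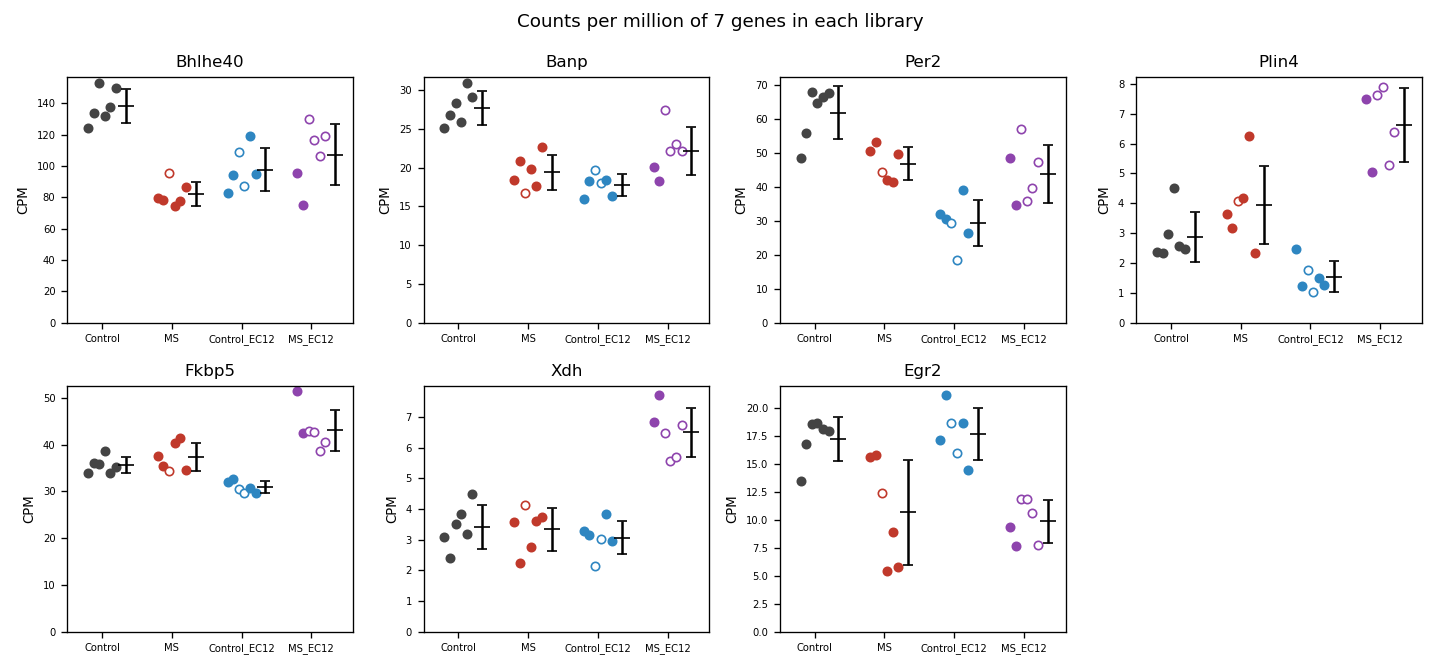
CPM of Bhlhe40, Banp, Per2, Plin4, Fkbp5, Xdh and Egr2 in each library by group, with open markers for the 7 libraries of GC slope above 0 and the bar at the right of each group giving the mean ± SD of 6 libraries. Bhlhe40 and Banp are highest in Control (138 and 27.7 CPM), Per2 is lowest in Control_EC12 (29.4 CPM), and Xdh (6.5 CPM), Plin4 (6.62 CPM) and Fkbp5 (43.1 CPM) are highest in MS_EC12.

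The supplement was next compared in separated mice, MS_EC12 against MS. Xdh, the enzyme that forms uric acid at the end of purine breakdown, rose from 3.34 ± 0.696 to 6.50 ± 0.802 CPM (log2 fold change 0.96 ± 0.153, adjusted p = 0.0294). Slc38a3, a glutamine transporter, rose from 66.8 ± 8.39 to 112 ± 25.5 CPM (0.74 ± 0.136, adjusted p = 0.036), and Abhd4, a lipase of N-acyl phospholipids, from 59.0 ± 9.15 to 85.3 ± 14.7 CPM (0.53 ± 0.104, adjusted p = 0.036). These 3 stood in the 17 libraries at 1.19, 0.91 and 0.49 and passed (adjusted p from 0.0379 to 0.0438). Also higher, at an adjusted p of 0.036, were Fam83d (0.97 ± 0.174), Tmem114 (1.01), Smim3 (0.77), AW047730 (0.69), Metrn (0.58), Syngr2 (0.58) and Pacsin3 (0.39). The gene model Gm32810 (−1.23 ± 0.219) and Gask1b (−0.56 ± 0.107) fell, both at an adjusted p of 0.036. None of these 9 passed in the 17 libraries (adjusted p from 0.0935 for Smim3 to 0.375 for Gask1b).

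In all, 28 genes were higher and 2 lower in MS_EC12 than in MS, with 5842 at an unadjusted p under 0.05. Xdh lies on chromosome 17 from 73883895 to 73950397 (Gene ID 22436) and Slc38a3 on chromosome 9 from 107651154 to 107668968 (Gene ID 76257). Below the 2 that fell came Cfap44 (−0.94, adjusted p = 0.0519), Sorcs3 (−0.45, adjusted p = 0.0533) and Bmp3 (−0.69, adjusted p = 0.0544). Of the candidates none passed, with Nr3c1, the glucocorticoid receptor, at −0.41 (adjusted p = 0.0856), Fkbp5 at 0.21 (adjusted p = 0.0843), Crhr1 at 0.39 (adjusted p = 0.0774), Bdnf at −0.42 (adjusted p = 0.0952), Mbp at 0.36 (adjusted p = 0.0976) and Oxtr at −0.21 (adjusted p = 0.19). Of the 6 genes that differed between MS and Control, Pdgfb rose in MS_EC12 against MS (0.54, adjusted p = 0.036), but not in the 17 libraries (0.28, adjusted p = 0.437). Bhlhe40 (0.39, adjusted p = 0.0774), Foxo6 (0.44, adjusted p = 0.0789), Banp (0.20, adjusted p = 0.144), Lrch4 (−0.57, adjusted p = 0.241) and 4930445K14Rik (0.03, adjusted p = 0.873) did not pass.

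Glucocorticoid-induced genes were higher with the supplement in separated mice, with a median of 0.318 over 22 members. Cdkn1a, a cyclin-dependent kinase inhibitor, passed over all genes (0.65 ± 0.131, adjusted p = 0.036; 0.49 in the 17 libraries, adjusted p = 0.351), and 7 were higher over the list alone (camera adjusted p = 0.00097; adjusted p = 0.628 with an estimated correlation). Antigen presentation and complement genes had a median of 0.4 over 21 members, with 0 passing and 12 higher over the list alone (adjusted p = 1.11e-05; adjusted p = 0.628 with an estimated correlation). C4b stood at 0.43, H2-D1 at 0.47, B2m at 0.34 and Tap1 at 0.55. Microglial genes had a median of 0.232 over 21 members, 12 higher over the list alone (adjusted p = 0.00287; adjusted p = 0.628 with an estimated correlation), with Tyrobp at 0.50. GABA receptor genes had a median of −0.444 over 16, 10 lower over the list alone (adjusted p = 0.00287; adjusted p = 0.628 with an estimated correlation), with Gabra2 at −0.71 and Gabrb1 at −0.67. Glutamate receptor genes stood at −0.258 over 24, with 3 higher and 11 lower over the list alone (adjusted p = 0.0197; adjusted p = 0.679 with an estimated correlation), and Grm5 at −0.64. No member of the last 3 lists passed over all genes.

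Ribosomal protein genes had a median of 0.311 over 77 members, 59 higher over the list alone (adjusted p = 2.84e-15; adjusted p = 0.679 with an estimated correlation), and nuclear respiratory chain genes 0.269 over 74, 47 higher over the list alone (adjusted p = 1.05e-12; adjusted p = 0.692 with an estimated correlation). Mitochondrially encoded genes stood at 0.134 over 13 (adjusted p = 0.0392; 5 higher over the list alone; adjusted p = 0.692 with an estimated correlation) and red blood cell genes at 0.746 over 7 (adjusted p = 0.00456; 5 higher over the list alone; adjusted p = 0.628 with an estimated correlation), with Hbb-bt at 0.83. None of their members passed over all genes.

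Of the 6 MS_EC12 libraries 4 had a GC slope above 0, against 1 of the 6 MS libraries. Of the 17 libraries 2 were MS_EC12, and there 11 genes were higher and 3 lower. Of these, 5 were among the 30 above: Xdh, Slc38a3, Abhd4 and, named after their values were seen, Cst3 and TrnL2. The list medians there were 0.194 for glucocorticoid-induced genes, 0.106 for antigen presentation and complement, 0.0599 for microglia, −0.109 for GABA receptors, −0.098 for glutamate receptors, 0.0591 for ribosomal proteins, 0.0437 for the nuclear respiratory chain, 0.265 for mitochondrially encoded genes and 0.794 for red blood cells, and each of these lists passed with the preset correlation. With the deposited TPM values, 21 genes were higher and 140 lower, against 28 and 2 on the counts. The number of genes changed, MS_EC12 vs MS, was 0 in place of 30 without MS replicate 1, 2, 4 or 6 or MS_EC12 replicate 6, 1 to 3 without MS replicate 5 or MS_EC12 replicate 3 or 4, and 3937, 5037 and 4594 without MS replicate 3, MS_EC12 replicate 1 and MS_EC12 replicate 2. Beside the counts of 0, edgeR called 30 genes and DESeq2 2036 in all libraries.

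Separated mice given the supplement were also set against Control. Nr4a3, a nuclear receptor of the immediate early class, fell from 52.0 ± 8.11 to 27.5 ± 6 CPM (log2 fold change −0.92 ± 0.14, adjusted p = 0.00488), and Slc7a11, the cystine and glutamate exchanger, changed by −0.93 ± 0.184 (adjusted p = 0.0181). Trpv4, a cation channel gated by osmotic stretch and heat, rose by 1.73 ± 0.264 (adjusted p = 0.00488), Xdh by 0.93 ± 0.153 (adjusted p = 0.00677) and Abhd4 by 0.63 ± 0.104. Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce, rose by 0.28 ± 0.0676 (adjusted p = 0.0274). Each of these 6 held in the 17 libraries, at −1.26, −0.68, 1.41, 1.10, 0.50 and 0.40. Trpv4 is also a member of the choroid plexus list, 1 of the tissues a dissection could carry in, which had a median of 0.781 over 14 members here with 3 called higher, without passing as a list (camera adjusted p = 0.185; adjusted p = 0.801 with an estimated correlation), and −0.00249 with 1 called in the 17 libraries. MS_EC12 replicate 6 held 24820 counts of the choroid plexus gene Ttr, and without it the log2 fold change of Trpv4, MS_EC12 vs Control, was 1.42 (adjusted p = 0.00896).

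The remaining genes of smallest p that rose were 4930445K14Rik (0.79), Pglyrp1, a peptidoglycan recognition protein (1.21), Eln, which encodes elastin (0.74), H2bc4 (0.56), Plin4, a coat protein of lipid droplets (1.2), Ppp1r10 (0.45) and Npc2 (0.41). Of these, 4930445K14Rik, Eln and H2bc4 held in the 17 libraries, and Pglyrp1 (adjusted p = 0.0642), Plin4 (adjusted p = 0.0718), Ppp1r10 (adjusted p = 0.0672) and Npc2 (adjusted p = 0.0575) did not. Those that fell were Ppp1r3c (−0.60), Slc5a3 (−0.77), P4ha1 (−0.56), Map3k13 (−0.49 ± 0.0918), Kmt5a (−0.31), Arhgef3 (−0.43), Trmt1l (−0.30) and Fam107b (−0.49). Of these, Ppp1r3c, Slc5a3 and Map3k13 held in the 17 libraries. P4ha1 (adjusted p = 0.0893), Kmt5a (adjusted p = 0.104), Arhgef3 (−0.23, adjusted p = 0.0677), Trmt1l (−0.19, adjusted p = 0.17) and Fam107b (adjusted p = 0.135) did not. Of the candidates, Adrb3, a beta-adrenergic receptor, rose by 0.58 ± 0.189 (adjusted p = 0.0457), and Nr3c1 (−0.52 ± 0.138, adjusted p = 0.0319) and Egr2 (−0.81 ± 0.206, adjusted p = 0.0298) fell; in the 17 libraries these 3 did not pass (adjusted p = 0.627, 0.198 and 0.132). Oxtr (−0.30, adjusted p = 0.0681), Mbp (0.34, adjusted p = 0.0668), Bdnf (−0.39, adjusted p = 0.0732), Arc (−0.64, adjusted p = 0.122) and Fos (−0.30, adjusted p = 0.141) did not pass.

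The number of genes changed, MS_EC12 vs Control, was 2594, 1344 higher and 1250 lower, with 7035 at an unadjusted p under 0.05. This count went with the GC slope: 4 of the 6 MS_EC12 libraries and 0 of the 6 Control libraries had a slope above 0. With the sign of the slope as a model term 14 genes passed. Among the 17 libraries, 2 of which were MS_EC12, 193 passed, 80 higher and 113 lower, and 76 genes were called in both. On the deposited TPM values the split was 613 higher and 3433 lower.

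Ribosomal protein genes had a median of 0.4, with 62 of 77 higher over all genes and 66 over the list alone (camera adjusted p = 8.94e-23; adjusted p = 0.538 with an estimated correlation), and nuclear respiratory chain genes 0.325, with 52 of 74 higher and 61 higher and 1 lower over the list alone (adjusted p = 1.14e-18; adjusted p = 0.538 with an estimated correlation). Rpl27 stood at 0.52, Fau at 0.56, Ndufb3 at 0.34 and Cox7c at 0.47. Their medians in the 17 libraries were 0.124 and 0.0955, with 4 and 3 members called. Antigen presentation and complement had a median of 0.395 with 9 of 21 higher, 13 higher and 1 lower over the list alone (adjusted p = 6.49e-05; adjusted p = 0.538 with an estimated correlation), and 0.0801 with 0 called in the 17 libraries, where the list lost its call (adjusted p = 0.136); C1qb stood at 0.54 and H2-D1 at 0.48. Microglial genes had a median of 0.276 with 8 of 21 higher, 13 over the list alone (adjusted p = 0.000893; adjusted p = 0.538 with an estimated correlation), and 0.0674 in the 17 libraries.

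Glucocorticoid-induced genes had a median of 0.264 with 8 of 22 higher, 10 higher and 1 lower over the list alone (adjusted p = 0.00314; adjusted p = 0.538 with an estimated correlation), among them Fkbp5, Plin4, the metallothionein Mt1 (0.52) and Cdkn1a (0.51); in the 17 libraries the median was 0.167 with 5 called, among which Plin4, Mt1 (0.29, adjusted p = 0.175) and Cdkn1a (0.29, adjusted p = 0.477) were not. Immediate early genes had a median of −0.205 over 35, with 1 higher and 4 lower both over all genes and over the list alone (adjusted p = 0.0228; adjusted p = 0.694 with an estimated correlation), and −0.401 with 7 lower in the 17 libraries. GABA receptor genes stood at −0.423 with 4 of 16 lower, 2 higher and 9 lower over the list alone (adjusted p = 0.0235; adjusted p = 0.555 with an estimated correlation), and glutamate receptor genes at −0.224 with 4 of 24 lower, 1 higher and 12 lower over the list alone (adjusted p = 0.018; adjusted p = 0.538 with an estimated correlation); Gabrb1 fell by 0.68, Grm5 by 0.61 and Gria3 by 0.71. Their medians in the 17 libraries were −0.038 and −0.0772 with 0 called, and the GABA receptor list lost its call (adjusted p = 0.268). Heat shock genes had a median of −0.253 with 1 higher and 6 lower of 20, 1 higher and 9 lower over the list alone (adjusted p = 0.0394; adjusted p = 0.538 with an estimated correlation), and −0.154 in the 17 libraries; Dnajb4 stood at −0.56 and Hsph1 at −0.41. Red blood cell genes had a median of 0.638 with 4 of 7 higher, 5 over the list alone (adjusted p = 0.0129; adjusted p = 0.538 with an estimated correlation), and 0.658 in the 17 libraries.

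Per library, 10 lists differed between MS_EC12 and Control by exact permutation after adjustment, each in 6 of 6 libraries. Mean log2 CPM was higher for ribosomal proteins by 0.349, the nuclear respiratory chain by 0.288, antigen presentation and complement by 0.292 and microglia by 0.201 (adjusted p from 0.0165 to 0.0411). Lower were glutamate receptors (−0.25), heat shock (−0.246), clock (−0.136), upper cortical layers (−0.134), cholesterol synthesis (−0.117) and corticosteroid signalling (−0.111; adjusted p from 0.0165 to 0.0411). No list passed in the other 4 comparisons between groups. In those, a list that alone reaches the smallest exact p, 0.00216, cannot pass after adjustment over the lists. The clock in MS against Control (−0.195) and antigen presentation in Control_EC12 against Control (0.31) reached it. Each did so in 6 of 6 libraries (adjusted p = 0.0823 for both, exact permutation). None passed in the 17 libraries. There the exact p cannot go below 0.0357 with 6 Control against 2 MS_EC12 libraries, and 9 of the 10 differences were also smaller. They were 0.132 for ribosomal proteins, 0.101 for the respiratory chain, 0.0739 for antigen presentation (exact p = 0.429), 0.109 for microglia (exact p = 0.214) and −0.0791 for glutamate receptors. They were −0.0648 for cholesterol synthesis, −0.0713 for corticosteroid signalling, −0.117 for upper layers and −0.216 for heat shock. The clock stood at −0.245. Without single libraries the number of genes changed, MS_EC12 vs Control, was 242, 315, 233, 370, 9 and 328 without Control replicate 1 to 6 in turn, and 6544, 6135, 126, 111, 489 and 10 without MS_EC12 replicate 1 to 6, against 2594 in all libraries.

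**Figure D3:**
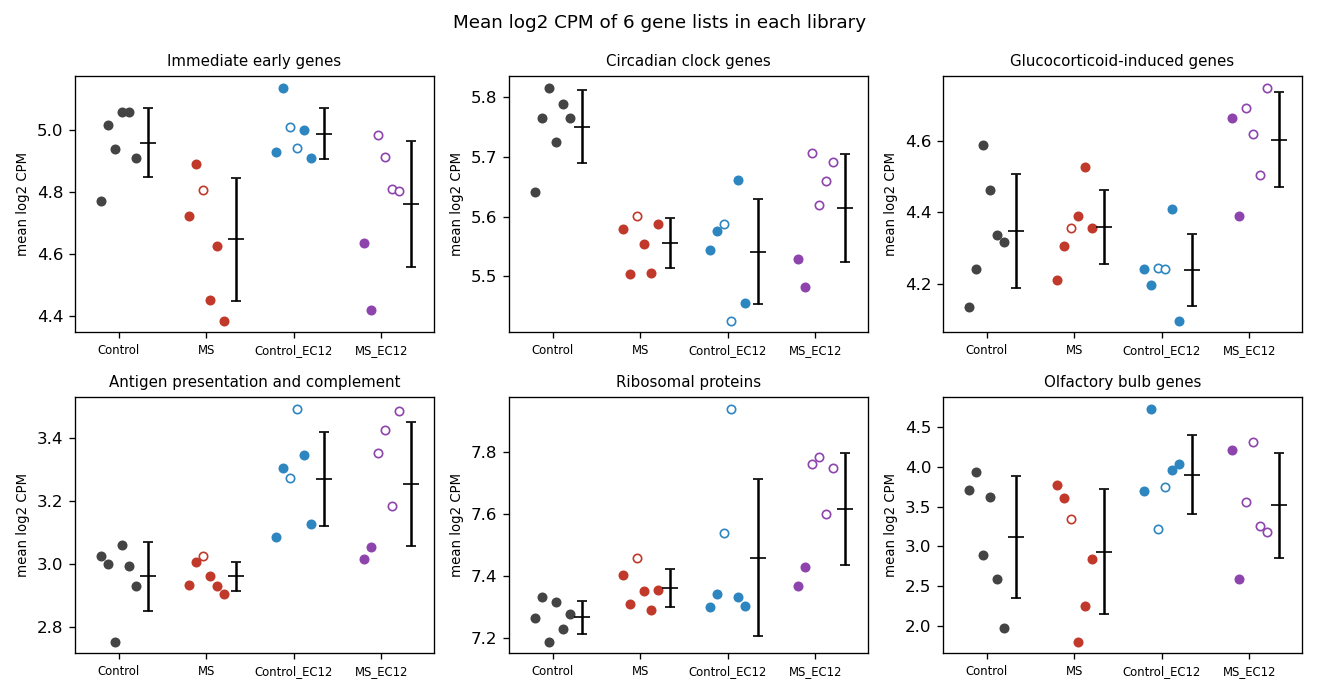
Mean log2 CPM of 6 gene lists (immediate early, circadian, glucocorticoid response, antigen presentation and complement, ribosomal protein, olfactory bulb) in each library by group, with open markers for the 7 libraries of GC slope above 0 and the bar at the right of each group giving the mean ± SD of 6 libraries. The immediate early mean is 4.96 in Control and 4.65 in MS, the glucocorticoid mean is highest in MS_EC12 (4.60), and the ribosomal mean is 7.27 in Control and 7.62 in MS_EC12, where most libraries have a GC slope above 0.

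Among mice given the supplement, MS_EC12 was compared with Control_EC12. Plin4 rose from 1.53 ± 0.513 to 6.62 ± 1.24 CPM (log2 fold change 2.11 ± 0.227, adjusted p = 3.01e-05), and Fkbp5 rose from 30.9 ± 1.25 to 43.1 ± 4.39 CPM (0.48 ± 0.0678, adjusted p = 0.00113). Xdh rose by 1.09 and the calcium-dependent kinase Camk1g by 0.84 (both adjusted p = 0.00113). Nr4a3 fell from 52.8 ± 8.51 to 27.5 ± 6 CPM (−0.94 ± 0.14, adjusted p = 0.00162) and Fos, the immediate early transcription factor, from 55.5 ± 7.15 to 34.0 ± 6.47 CPM (−0.71 ± 0.151, adjusted p = 0.042). Thbs1, a secreted matrix protein, changed by −1.02 ± 0.158 (adjusted p = 0.00215). All of these passed in the 17 libraries except Fos (−0.99, adjusted p = 0.0777).

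In this comparison 37 genes were higher and 11 lower, with 2924 at an unadjusted p under 0.05. Plin4 lies on chromosome 17 from 56100587 to 56109948 (Gene ID 57435), Fkbp5 on chromosome 17 from 28398753 to 28486149 (Gene ID 14229) and Nr4a3 on chromosome 4 from 48045078 to 48086447 (Gene ID 18124). Smim3 (0.97), Hspa12b (0.78), Prr5 (0.63), Pglyrp1 (1.17), Map3k6 (0.82 ± 0.144) and Smad3 (0.51) completed the 10 that rose. Insig1 (−0.39), Pak7 (−0.76), Lama4 (−0.60), Ninl (−0.79), Arhgap42 (−0.79), Rflnb (−0.32) and Pclaf (−1.0) completed the 10 that fell. Of these 2 sets Smim3 and Pak7 passed in the 17 libraries, and the others did not (adjusted p from 0.0552 for Map3k6 to 0.391 for Pclaf). Egr2 stood at −0.84 without passing (adjusted p = 0.1).

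Glucocorticoid-induced genes had a median of 0.306 over 22 members, 18 of them positive (camera adjusted p = 4.07e-07; adjusted p = 0.206 with an estimated correlation). Over all genes 5 rose, namely Plin4, Fkbp5, Map3k6, Hif3a (1.19, adjusted p = 0.0339) and Zbtb16 (0.68, adjusted p = 0.0444), and over the list alone 9 were higher and 1 lower. The median in the 17 libraries was 0.239 with 5 called, among them Plin4, Fkbp5 and Hif3a but neither Map3k6 nor Zbtb16 (0.57, adjusted p = 0.179). Immediate early genes had a median of −0.169 over 35, with 2 lower over all genes and 2 higher and 11 lower over the list alone (adjusted p = 0.00161; adjusted p = 0.721 with an estimated correlation), and −0.393 with 4 lower in the 17 libraries. Meningeal fibroblast genes stood at −0.263 over 23 members, with 1 lower over the list alone (adjusted p = 0.000159), striatal genes at 0.252 over 25 (adjusted p = 0.0185) and red blood cell genes at 0.439 over 7, with 5 higher over the list alone (adjusted p = 0.0137). Respiratory chain genes had a median of 0.193 (adjusted p = 6.05e-13), ribosomal protein genes 0.172 (adjusted p = 3.17e-10) and microglial genes 0.102 (adjusted p = 0.0456). For each of the last 6 lists the adjusted p was 0.721 with an estimated correlation. Of these 6, microglia lost its call in the 17 libraries (0.0758, adjusted p = 0.268). The others passed, at −0.27 for meningeal fibroblasts, 0.252 for striatal genes, 0.528 for red blood cells, 0.102 for the respiratory chain and 0.0728 for ribosomal proteins.

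The GC slope was above 0 in 4 MS_EC12 and 2 Control_EC12 libraries. Of the 48 genes 10 were among the 31 called in the 17 libraries (12 higher, 19 lower). Without single libraries the count of genes changed, MS_EC12 vs Control_EC12, was 17, 29, 186, 129, 20 and 14 without Control_EC12 replicate 1 to 6 in turn, and 169, 158, 18, 25 and 16 without MS_EC12 replicate 1, 2, 3, 5 and 6.

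The interaction asked whether the effect of the supplement differed between rearing conditions. It passed for 2 genes, Banp (0.84 ± 0.128, adjusted p = 0.0152) and Bhlhe40 (0.89 ± 0.152, adjusted p = 0.0379), with 882 genes at an unadjusted p under 0.05. Banp averaged 27.7 ± 2.16, 19.4 ± 2.22, 17.8 ± 1.4 and 22.2 ± 3.08 CPM in Control, MS, Control_EC12 and MS_EC12, and Bhlhe40 averaged 138 ± 10.9, 81.9 ± 7.78, 97.7 ± 13.7 and 107 ± 19.6 CPM (SD, n = 6), so both genes were highest in Control. Next came Plin4 (1.65, adjusted p = 0.112), Xdh (1.11, adjusted p = 0.144), Per2 (0.98, adjusted p = 0.152), Usp43 (−0.75, adjusted p = 0.176), Fkbp5 (0.41, adjusted p = 0.238) and Creb5 (−1.01, adjusted p = 0.238), none of which passed.

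Of the lists, glucocorticoid-induced genes had an interaction with a median of 0.269 over 22 members, 6 higher over the list alone (adjusted p = 1.89e-07; adjusted p = 0.0779 with an estimated correlation), and 0.28 in the 17 libraries. Clock genes had a median of 0.279 over 18, with Bhlhe40 passing and 8 higher over the list alone (adjusted p = 1.73e-07; adjusted p = 0.0779 with an estimated correlation), and 0.113 in the 17 libraries. Respiratory chain genes stood at 0.109 (adjusted p = 0.000522; adjusted p = 0.941 with an estimated correlation), junction genes of the blood-brain barrier at 0.141 with 2 higher over the list alone (adjusted p = 0.0189; adjusted p = 0.408 with an estimated correlation) and red blood cell genes at 0.548 (adjusted p = 0.0189; adjusted p = 0.941 with an estimated correlation). Barrier junctions lost their call in the 17 libraries (0.129, adjusted p = 0.137), and the respiratory chain (0.0509) and red blood cells (0.665) passed. In the 17 libraries Banp (0.63, adjusted p = 0.182) and Bhlhe40 (0.61, adjusted p = 0.332) did not pass, and Nectin3 (−0.69) and Jun (−0.68), named after their values were seen, did. The number of genes changed, interaction of MS and EC-12, was 4 without Control replicate 2 and 1 without Control replicate 3, 4, 5 or 6, MS replicate 1, 2, 4 or 6, Control_EC12 replicate 2, 4 or 6, or MS_EC12 replicate 3, 4, 5 or 6.

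The series also asks whether the supplement reverses effects of maternal separation. Across 18380 genes, the correlation of log2 fold changes of MS against Control with those of MS_EC12 against MS was −0.0909, with a covariance of −0.00614. Because MS libraries enter both with opposite sign, unchanged groups gave a mean correlation of −0.49 (95% of values from −0.778 to −0.0894) and a mean covariance of −0.0235. The observed correlation was less negative than the chance mean, and the covariance exceeded its chance mean by 0.0173, so no reversal beyond chance was seen across genes. Counted by distance from the chance mean, the correlation passed (permutation p = 0.0259, 2-sided), but −0.0909 lay inside the 95% range. A difference from chance is therefore not firmly placed. With the MS libraries split into sets of 3, 1 set for each comparison, the mean correlation over 20 assignments was 0.13 (from −0.115 to 0.356). The correlation in the 17 libraries was −0.321 against a chance mean of −0.389 (permutation p = 0.669). The distance from the chance mean, which is opposite in direction to a reversal of MS changes by EC-12, also no longer passed without MS replicate 3 (−0.351, permutation p = 0.211) or without MS_EC12 replicate 6 (−0.157, permutation p = 0.0589).

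Responses to the supplement in Control-reared and MS-reared mice, which share no library, correlated across genes at 0.47 (covariance 0.0387), and 72% of genes had the same sign. Chance arrangements within each rearing gave −0.438 to 0.438 (95% of 853776 arrangements; exact permutation p = 0.03, 2-sided). The correlation in the 17 libraries was 0.199 (chance −0.193 to 0.194, exact permutation p = 0.0433). Both supplement groups held more libraries of GC slope above 0 than their reference. The numbers were 2 in Control_EC12 against 0 in Control and 4 in MS_EC12 against 1 in MS. A library batch of GC content could therefore give agreement of this sign too, and the permutation does not cover it. The agreement of EC-12 changes in MS and Control mice did not pass for genes of mean log2 CPM above 3 (0.722, exact permutation p = 0.0816) or by Spearman's method (0.542, permutation p = 0.0509 from random draws, too close to 0.05 to place it firmly on either side). It also no longer passed without Control replicate 1 (0.428, p = 0.0593), MS replicate 5 (0.44, p = 0.0514), Control_EC12 replicate 3 (0.269, p = 0.0512), Control_EC12 replicate 4 (0.368, p = 0.0713) or MS_EC12 replicate 4 (0.433, p = 0.0546; exact permutation).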

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

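The tests on the 193 genes of the 17 libraries, on splits that keep the libraries of GC slope above 0 together, on immediate early genes, on the clock, on glucocorticoid-induced genes in the 17 libraries, and on the immediate early and glucocorticoid-induced lists with the trend on GC content removed were chosen after the result was seen.

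The 2594 genes that differed between MS_EC12 and Control went with the GC slope, which was above 0 in 4 MS_EC12 and 0 Control libraries. Of genes tested in the 17 libraries 193 passed, and of the 28 splits of their Control and MS_EC12 libraries 1, the real one, gave as many (highest other 1), but the slope there was also lower in both MS_EC12 libraries (−0.182 and −0.17) than in every Control library (−0.148 to −0.0761), so a library batch of GC content cannot be told apart from the groups for those calls. Of the 2518 calls not held there, 97.4% had the sign of the difference between libraries of slope above and below 0 estimated in MS and Control_EC12 alone, against 81.6% of the 76 held and 80.5% of the 15786 genes not called, and a batch is a candidate explanation for them. All 12 libraries were split in 28 ways that kept the 4 of slope above 0 together. Of these, 3 gave as many genes as the real groups (highest other 3807, median 0). The 4 were all MS_EC12, so this cannot tell batch from group. An effect of separation and supplement together stays open for both parts of the calls.

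Immediate early genes were lower in MS than Control (median −0.302, adjusted p = 0.0605 with an estimated correlation), and clock genes were lower than Control in MS (median −0.14, adjusted p = 0.0605 with an estimated correlation) and in Control_EC12 (median −0.191, adjusted p = 0.162 with an estimated correlation). The 17 libraries called 5 immediate early genes lower and 0 higher, but the slope there was also lower in every MS library (−0.219 to −0.156) than in every Control library (−0.148 to −0.0761), which leaves a library batch of GC content open for those calls. In all libraries, each library's trend on GC content and length was also removed. The mean log2 CPM of the immediate early list then differed by −0.283, against −0.311 before. After removal the SD was 0.172 in MS and 0.11 in Control (n = 6, exact permutation p = 0.00649). The mean slopes on GC content were close in all libraries, at −0.107 in MS and −0.114 in Control. Removing the trend could therefore move this difference little, and the result cannot decide whether a library batch lies behind it. The removal was not made in the 17 libraries, where the slope parted MS from Control. A shift of clock phase may lie behind the clock genes. The test set for it was whether Arntl, Clock, Npas2, Cry1 and Nfil3, which peak apart from the Per and Nr1d genes, were higher on balance. Their mean log2 CPM differed from Control by −0.0591 in MS (exact permutation p = 0.175) and by −0.0642 in Control_EC12 (exact permutation p = 0.251). In Control_EC12 Cry1 was lower and Nfil3 higher, neither passing, so the mean joins members that moved opposite ways. Without a time of collection the direction that a shift would give is not known either, so this test cannot decide. The labels used here give no time of collection and no handling before it, so these stay open beside separation and the supplement themselves.

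Glucocorticoid-induced genes were higher in MS_EC12 than in Control_EC12 (median 0.306, adjusted p = 0.206 with an estimated correlation). The 17 libraries called 5 members higher and 0 lower, among them Plin4, Fkbp5 and Hif3a but neither Map3k6 nor Zbtb16, but the slope there was also lower in both MS_EC12 libraries (−0.182 and −0.17) than in every Control_EC12 library (−0.16 to −0.0893), which leaves a library batch of GC content open for those calls. With each library's trend on GC content and length removed, the mean log2 CPM of the list still differed by 0.336 (SD 0.112 in MS_EC12 and 0.108 in Control_EC12, n = 6; exact permutation p = 0.00433), which argues against that trend as the whole cause. Without that removal it differed by 0.363 ± 0.0681 (SE), above the largest upper bound of the endothelial, mural and astrocyte scores (0.219, at 2 standard errors), which argues against more RNA of those cells as the whole cause. A difference in glucocorticoid exposure between rearing conditions under the supplement is a possible explanation that was not tested, and handling at collection, which the labels used here do not give, stays open too.

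Single libraries that lay far from the other 5 of their group were looked for with Dixon's criterion, which by chance singles out about 1 in 20 groups. Of 200 groups tested 18 had such a library, against 10 by chance. The GC slope was 0.283 in MS replicate 3 (others −0.219 to −0.156) and 0.465 in Control_EC12 replicate 3 (others −0.16 to 0.0429), and the length slope was −0.183 in Control_EC12 replicate 4 (others −0.00491 to 0.0393). In mean log2 CPM of lists, MS replicate 3 was low for interferon-stimulated genes (0.92, others 1.24 to 1.42) and high for the nuclear respiratory chain (6.92, others 6.76 to 6.81). Control_EC12 replicate 4 was low for postsynaptic genes (7.28, others 7.5 to 7.61) and high for ribosomal proteins (7.94, others 7.3 to 7.54) and microglia (4.9, others 4.54 to 4.61). Control_EC12 replicate 3 was low for heat shock genes (6.12, others 6.34 to 6.45), and MS replicate 6 was low for barrier junctions (3.9, others 4.02 to 4.09) and high for cholesterol synthesis (5.73, others 5.61 to 5.65).

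MS replicate 1 was low for microglia (4.44, others 4.55 to 4.6), Control replicate 5 low for oligodendrocyte precursors (5.1, others 5.21 to 5.25) and Control replicate 6 high for striatal genes (6.06, others 5.77 to 5.87). MS_EC12 replicate 1 was low for myelin genes (5.36, others 5.96 to 6.14), and MS_EC12 replicate 6 was high for choroid plexus genes (3.36, others 0.677 to 1.08). Of the plotted genes, Plin4 reached 4.51 CPM in Control replicate 4 (others 2.34 to 2.97) and Fkbp5 51.4 CPM in MS_EC12 replicate 1 (others 38.6 to 43).

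The effect of the supplement differed between rearing conditions, by the interaction, for Bhlhe40 (log2 difference 0.89) and Banp (0.84) in all 24 libraries, but neither passed in the 17 libraries (0.61, adjusted p = 0.332, and 0.63, adjusted p = 0.182). It also differed for 5 lists by the preset-correlation test, with mean log2 differences of 0.377 for glucocorticoid-induced genes, 0.266 for clock genes, 0.0831 for the nuclear respiratory chain, 0.182 for barrier junctions and 0.419 for red blood cells. With an estimated correlation none of the 5 passed (adjusted p = 0.0779 for the first 2 of these, then 0.941, 0.408 and 0.941).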

How the results depend on the processing

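The settings with the 17 libraries, the 7 libraries, GC or length terms, TPM values, and removal of ribosomal RNA and mitochondrial genes were chosen after the data were seen. Counts stand below in this order: genes changed, MS vs Control (6 in the main setting), genes changed, MS_EC12 vs MS (30), genes changed, Control_EC12 vs Control (4), genes changed, MS_EC12 vs Control (2594), genes changed, MS_EC12 vs Control_EC12 (48) and genes changed, interaction of MS and EC-12 (2). RLE size factors and removal of ribosomal RNA and mitochondrial genes left all 6 counts within 1.5 times. Where counts moved, the cause was not tested, apart from the fewer libraries or genes that some settings use. DESeq2 gave 23, 2036, 86, 4547, 196 and 19. Voom with quality weights gave 157, 9432, 236, 9627, 8959 and 7321. An adjusted p under 0.1 gave 17, 2580, 24 and 5860 for the first 4. Surrogate variables gave 86, 2, 276, 56, 120 and 28. Without a filter MS_EC12 vs MS gave 1, MS_EC12 vs Control 339 and the interaction 1. With only the groups compared in the fit, MS vs Control gave 13, MS_EC12 vs MS 0, Control_EC12 vs Control 2 and MS_EC12 vs Control_EC12 2. Beside that 0, 5842 genes had an unadjusted p under 0.05 in the edgeR fit of all groups. The sign of the GC slope as a term gave 41, 1, 38 and 14 for the first 4 and 14 for the interaction, GC and length slopes gave 126, 5, 162, 112, 253 and 25, and GC and length offsets gave 22 for MS vs Control, 59 for Control_EC12 vs Control, 121 for MS_EC12 vs Control_EC12 and 5 for the interaction, with 30 higher and 9 lower for MS_EC12 vs MS. The 17 libraries gave 83, 14, 87, 193 and 31, and for the interaction 2 genes, neither shared. The 7 libraries alone allowed only MS_EC12 vs MS and MS_EC12 vs Control_EC12, with 0 in edgeR in each, where DESeq2 was run on all 24 only and 5842 and 2924 genes had an unadjusted p under 0.05 in all 24. TPM values gave 161 for MS_EC12 vs MS (21 higher, 140 lower), 2 for Control_EC12 vs Control, 4046 for MS_EC12 vs Control (613 higher, 3433 lower), 16 for MS_EC12 vs Control_EC12 and, with limma, 0 for the interaction, beside 882 at an unadjusted p under 0.05 on the counts. Removing each library in turn gave 2 to 8, 0 to 5037, 4 to 24, 9 to 6544, 14 to 186 and 1 to 4. For MS_EC12 the largest rises were from 30 to 5037 against MS, 2594 to 6544 against Control and 48 to 186 against Control_EC12. Each came without a library whose GC slope had the other sign from most of its group. These rises went with how group and slope line up, and fewer libraries alone do not account for them.

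The replicate number as a block gave 10, 3809, 33, 5939, 232 and 9 for genes changed, MS vs Control, genes changed, MS_EC12 vs MS, genes changed, Control_EC12 vs Control, genes changed, MS_EC12 vs Control, genes changed, MS_EC12 vs Control_EC12 and genes changed, interaction of MS and EC-12. The numbers were not taken to pair libraries, as not every pair had deviations correlated above 0.1. Of 36 same-numbered pairs (−0.548 to 0.847) 23 did, with all 6 of replicate 1 (0.246 to 0.66). Of 24 libraries 7 correlated best with their own number. A factor shared by number stays open. The block left list counts within 1.5 times and moved neither correlation.

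Lists passing numbered 8, 9, 19, 10, 8 and 5 in the same order. An estimated correlation gave 0 in each, with 24 or with 17 libraries. The fry test gave 0 for MS vs Control, 3 for Control_EC12 vs Control and 2 each for MS_EC12 vs Control_EC12 and the interaction. The sign of the GC slope as a term gave 20 for MS_EC12 vs MS and 20 for MS_EC12 vs Control, and the 17 libraries gave 22 and 17 for these, 13 for MS_EC12 vs Control_EC12 and 9 for the interaction. For the direction of list oxphos_nuclear, Control_EC12 vs Control, the sign turned in the 17 libraries, with p = 0.115, and p = 0.609 with an estimated correlation. Library scores passing in MS_EC12 against Control numbered 10, and 0 in the 17 libraries, where 6 against 2 libraries cannot pass, and 2 passed in Control_EC12 against Control with medians in place of means.

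The reversal of MS changes by EC-12 (correlation −0.0909) was less negative than chance, which is opposite to a reversal. That difference from chance no longer held for genes of mean log2 CPM above 3 (0.207), by Spearman's method (0.0325), with MS libraries in separate sets (0.13), with the sign of the GC slope as a term (−0.357) or in the 17 libraries (−0.321), and ran from −0.351 to −0.0352 with each library left out. The agreement of EC-12 changes in MS and Control mice (0.47) lost its place beyond chance for genes of mean log2 CPM above 3 (0.722) and, by a margin within the error of its random draws, by Spearman's method (0.542), and ran from 0.269 to 0.527. Of the 68 calls among genes that the naming rule took 65 held with RLE size factors, 48 without a filter, 34 of 66 with only the groups compared, 47 with surrogate variables, 38 with the sign of the GC slope as a term and 33 in the 17 libraries. DESeq2, voom with weights and the block lost none of those they tested, and none reversed in any of these settings. Each of DESeq2, voom with weights and the block called more genes than the main setting in every comparison, so keeping these calls is a weak check. The lowest voom weights (0.156 to 0.278) went to the libraries whose GC slope had the other sign from most of their group. That setting therefore does not separate the groups from the slope. Over single libraries left out, 596 of 840 calls held. Depth limits genes below the count filter, which were not tested. The pseudocount planned for TPM values in place of counts was not run, because counts were given.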

Other observations

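The genes and counts of the 17 libraries, the tests on those libraries, and the splits that keep the balance of libraries of GC slope above 0, were chosen after the result was seen; the tests on splits of all libraries were planned.

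Nectin3, an adhesion molecule of synapses, was higher than Control in the 17 libraries both in MS (0.39, adjusted p = 0.00119) and in Control_EC12 (0.46, adjusted p = 0.000856), and the corepressor Cbfa2t3 was lower in both (−0.57, adjusted p = 0.00145, and −0.56, adjusted p = 0.00439). The same Control libraries enter both comparisons. Jun was lower there in MS_EC12 than in Control_EC12 (−0.80, adjusted p = 0.000689) and Fosb too (−1.21, adjusted p = 0.0148), with −0.32 and −0.57 in all libraries (adjusted p = 0.241 and 0.173).

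Several lists passed in none of the 6 comparisons by the preset-correlation camera test in all 24 libraries. Their smallest adjusted p was 0.0618 for monoamine genes, 0.0625 for oligodendrocyte precursors and for choroid plexus, 0.065 for astrocytes, 0.124 for deep and 0.138 for upper cortical layers, 0.14 for cholesterol synthesis, 0.242 for neuroinflammation, 0.279 for the perineuronal matrix, 0.28 for thalamus and midbrain, 0.314 for corticosteroid signalling, 0.327 for interneurons and 0.519 for myelin. By library scores, upper layers, cholesterol synthesis and corticosteroid signalling did differ between MS_EC12 and Control (adjusted p = 0.0165, 0.0308 and 0.0165).

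In the 17 libraries some of these lists passed with the preset correlation, and none did with an estimated correlation (adjusted p from 0.203 to 0.994). Myelin genes were lower in MS than Control (median −0.0674, adjusted p = 0.0386). They were also lower in MS_EC12 than in MS (−0.191, adjusted p = 1.3e-05), than in Control (−0.238, adjusted p = 1.91e-08) and than in Control_EC12 (−0.25, adjusted p = 2.13e-08), and lower by the interaction (−0.176, adjusted p = 0.000139). In all libraries the medians of MS_EC12 were of opposite sign (0.163 against MS, 0.155 against Control and 0.0588 against Control_EC12), and MS_EC12 replicate 1, low for myelin, was 1 of the 2 MS_EC12 libraries among the 17. Also lower in MS_EC12 than in MS were corticosteroid signalling (−0.118, adjusted p = 0.035), monoamine genes (−0.0951, adjusted p = 0.0195) and deep layers (−0.112, adjusted p = 0.0433). Monoamine genes (−0.137, adjusted p = 0.00792) and upper layers (−0.119, adjusted p = 0.0126) were lower in MS_EC12 than in Control. The perineuronal matrix was lower in MS_EC12 than in Control_EC12 (−0.112, adjusted p = 0.0189). In Control_EC12 against Control deep layers were lower (−0.112, adjusted p = 0.025) and astrocyte genes higher (0.111, adjusted p = 0.00589).

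Some transcripts of neighbouring tissues were uneven between libraries. Ttr, the transthyretin gene of the choroid plexus, had 24820 counts in MS_EC12 replicate 6 and 1847 in MS replicate 3. Oxt had 740 counts in MS_EC12 replicate 6 and 241 in MS replicate 1. Omp, a gene of olfactory neurons, was spread more widely, from 18 to 1050 counts over the libraries.

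Other splits of the same libraries into groups of the same sizes were tested for the counts of genes, with 60 splits in each case. In MS against Control 1 split, the real one, gave as many (6, highest other 2). The same held in MS_EC12 against MS (30, highest other 5), Control_EC12 against Control (4, highest other 1) and MS_EC12 against Control (2594, highest other 0). For MS and Control_EC12 against Control these counts are small, and chance is unlikely but not excluded. For MS_EC12 against MS it can be excluded only among splits that mostly mix the 5 libraries of GC slope above 0. The splits that keep their balance of 4 and 1 number 11, too few for a share under 0.05 (real 30, highest other 5). For MS_EC12 against Control it can be excluded only among splits that mostly mix the 4 libraries of GC slope above 0, since 3 of the 28 splits that keep them together gave as many. For MS_EC12 against Control_EC12 4 splits gave as many as the real 48, so chance cannot be excluded. Of the 31 splits with the real balance of libraries of slope above 0, 1, the real one, gave as many (highest other 0). The highest other split, with 10131 genes, had all 6 libraries of GC slope above 0 on 1 side, a structure of the libraries; the 17 libraries gave 31 genes there. For the interaction 2 splits, the real one included, gave as many as the real 2 genes. The other one gave 3775 genes, which points to a structure of the libraries other than the groups. In 18 of the 60 splits at least the real 882 genes had an unadjusted p under 0.05 (highest other 7534), so chance is excluded at most for the count of 2 itself. Among the 17 libraries chance can be excluded by this count for MS against Control (1 of 60 splits; 83, highest other 2) and for MS_EC12 against Control (1 of 28; 193, highest other 1), although the GC slope parted the groups of both comparisons there too. For Control_EC12 against Control 2 of 60 splits, the real one included, gave as many as the real 87. The other one gave 130, more than the real groups, so chance is excluded at most for the count of 87 itself. By genes at an unadjusted p under 0.05, as many as the real count were reached in all libraries by 2 of 60 splits for MS against Control, 1 for MS_EC12 against MS, 1 for Control_EC12 against Control, 2 for MS_EC12 against Control and 10 for MS_EC12 against Control_EC12. The 17 libraries gave 5 of 60 for MS against Control (real 2052, highest other 2374), so by this measure chance cannot be excluded there. They gave 2 of 60 for Control_EC12 against Control (real 2661, highest other 3027) and 1 of 28 for MS_EC12 against Control.

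For the counts of lists, as many were reached by 25 of 60 splits in MS against Control (8, highest other 16), 46 in MS_EC12 against MS (9, highest other 21), 31 in MS_EC12 against Control (10, highest other 20), 50 in MS_EC12 against Control_EC12 (8, highest other 20) and 55 in the interaction (5, highest other 18), so chance cannot be excluded for these. For Control_EC12 against Control 2 of 60 splits gave as many as the 19 lists (highest other 21), so chance is not firmly excluded. In the 17 libraries it cannot be excluded for any count of lists tested, with 17 of 60 splits for Control_EC12 against Control (13, highest other 18), 39 of 60 for MS against Control (10, highest other 17) and 3 of 28 for MS_EC12 against Control (17, highest other 18).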
